A study of Mus musculus with 50 samples.

How the data were processed

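RNA was measured in 50 libraries of mouse embryos in 9 groups, 3 treatments at 3 stages. Per the labels, mRNA was injected at 200 ng/µl at 24 h after hCG, and pools of 5 embryos were collected at 28 to 30 h (late 1C), 32 h (early 2C) and 48 h (late 2C). Libraries were made with SMART-Seq v4 and Nextera XT and read in pairs of 75 nt on a NovaSeq. Duxbl libraries carried replicate numbers 4 to 7 at late 1C, 3 to 7 at early 2C and 1, 3, 4, 6 and 7 at late 2C, and the other groups 1 and 3 to 7.

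The deposited table held signal values for 35750 genes, made by the authors by multiplying the read counts of each library by 1 factor and rounding to whole numbers. This was read from the values, which skip or repeat whole numbers in a regular pattern in each library, with at least 99.17% of low values on the steps. The worth of 1 read was between 0.473 and 1.996, above 1 in 20 libraries, and 4 libraries allowed more than 1 step. Read numbers are therefore estimates, and whole reads were not recovered. The authors' notes name Trimmomatic 0.39, STAR 2.7.10a, Picard 3.0.0, featureCounts 2.0.4, DESeq2 1.36.0 and DESeq, and genome build mm39, without their roles. The strand setting, the annotation release and the handling of duplicates and reads with many positions are not stated. No pair among 116 pairs of replicates was identical.

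The design fixed before the data were examined had assumed read counts. Because the values are scaled, genes were tested with limma 3.58.1 (trend, in R 4.3.3) on log2(CPM + 0.5), with trimmed mean of M values scaling (30% and 5% trims) written for the purpose. Genes needed at least 0.5 CPM in as many libraries as the smallest group held. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The 3 groups of a stage shared a fit, as did the 3 uninjected groups, and the 6 mCherry and Duxbl groups shared a fit for the interaction. CPM values are on the scale of the fit a comparison belongs to, so those of a group differ slightly between fits. Replicates 4 and 5 lay apart from the others on principal component 1 at late 1C (32.8% of the variance), 2 at early 2C (18.7%) and 1 at late 2C (40.8%). The late 2C components were computed without the Duxbl libraries.

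Gene lists fixed before the data were examined were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, and 23 had at least 3 tested genes. Stage gene sets came from the uninjected libraries at an absolute log2 fold change of at least 1. They were tested in a fit of the Duxbl and mCherry groups alone, whose calls differ somewhat from those of the fit of 3 groups. Stage progress is the mean log2 CPM of the rising set minus that of the falling set, scaled to 0 and 1 at the uninjected means, and was compared by an exact permutation test.

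Genes were named by a rule set beforehand. It took the Dux and Duxbl models, the 8 largest changes in each direction in Duxbl against mCherry embryos (5 elsewhere) with at least 10 CPM in the higher group, no overlap between groups and no predicted name, and up to 4 genes per list by adjusted p. Other genes are said to have been chosen after their values were seen, as are Pramel25 and the genes of developmental families. Libraries with the same replicate number had residual correlations above 0.1 in every pair for Duxbl against mCherry at late 1C (0.41 to 0.58) and early 2C (0.17 to 0.48), mCherry against uninjected at late 1C (0.13 to 0.6) and Duxbl against uninjected at late 1C (0.16 to 0.49) and early 2C (0.11 to 0.4). In that order, 2 of 4, 4 of 5, 3 of 6, 3 of 4 and 2 of 5 libraries correlated best with their own number. The split of replicates 4 and 5 could give such correlations, so pairing by number stays uncertain. The main fits held no replicate block.

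The method was tested on simulated data. In Duxbl against mCherry designs it recovered 55.2%, 79.1% and 95.5% of changes of 2, 4 and 8 times at late 1C, 53.7%, 91.0% and 86.4% at early 2C and 16.4%, 61.2% and 75.8% at late 2C, with 11 false calls of 164, 7 of 161 and 4 of 106. Only 66 or 67 genes per size of change were altered, up and down alike. Libraries were drawn independently, without the split of replicates 4 and 5. These rates need not hold for the real libraries, least at late 2C, where 55.6% of genes were called. Alternatives planned beforehand were median of ratios scaling, no filter, limma voom with sample weights, other sets of groups in the fit, the replicate block, an estimated correlation, a set threshold of 2 and leaving out each library. Pseudocounts of 0.1 and 1, the deposited scale, a term for replicates 4 and 5 and the replicates taken apart were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.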

Results

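The series holds 50 RNA-seq libraries of mouse embryos (C57BL6/J), each made from a pool of 5 embryos. Embryos were left uninjected or injected at the 1-cell stage with mRNA for NLS-mCherry, a nuclear red fluorescent protein, or for Duxbl, a homeobox transcription factor of the Dux family, tagged with V5 and joined to the same reporter. They were collected at the late 1-cell (late 1C), early 2-cell (early 2C) and late 2-cell (late 2C) stages. There were 6 uninjected and 6 mCherry libraries per stage, and 4, 5 and 5 Duxbl libraries at late 1C, early 2C and late 2C. The labels do not say whether replicates came from separate litters. Deposited totals ran from 12044838 to 26956849 per library, which corresponds to an estimated 13013648 to 40676087 reads. Values below are mean CPM (signal scaled to a library total of 1e+06) ± SD over libraries. Log2 fold changes are on the log2(CPM + 0.5) scale, which understates the change of low genes, with a standard error (SE) and an adjusted p from limma.

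The injected transcript was read first, as a check of the labels. Duxbl1 (ENSMUSG00000048502, chromosome 14, 25979001 to 25990512, mm39) stood at 3613 ± 575 CPM in Duxbl late 1C embryos (n = 4) and at 128 ± 17.6 CPM in mCherry embryos (n = 6). At early 2C it stood at 2798 ± 979 CPM (n = 5) against 160 ± 37.2 CPM (n = 6), and at late 2C at 3125 ± 1150 CPM (n = 5) against 394 ± 152 CPM (n = 6). The log2 fold changes were 4.82 (SE 0.16, adjusted p = 5.64e-14), 4.07 (SE 0.22, adjusted p = 2.35e-10) and 3 (SE 0.41, adjusted p = 1.99e-06), and every Duxbl library lay above every mCherry library of its stage. The table holds no Duxbl2 or Duxbl3 model, so reads of these near-identical copies cannot be placed, and injected and endogenous Duxbl transcripts cannot be separated. Duxf3, the other Dux model in the table, stood at 1.67 ± 1.44 CPM in Duxbl and 2.51 ± 1.75 CPM in mCherry late 1C embryos and did not pass the test there (adjusted p = 0.91) or at early 2C (2.31 ± 0.379 against 3.40 ± 2.32 CPM, adjusted p = 1). At late 2C it was below the minimum for testing.

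**Figure D1:**
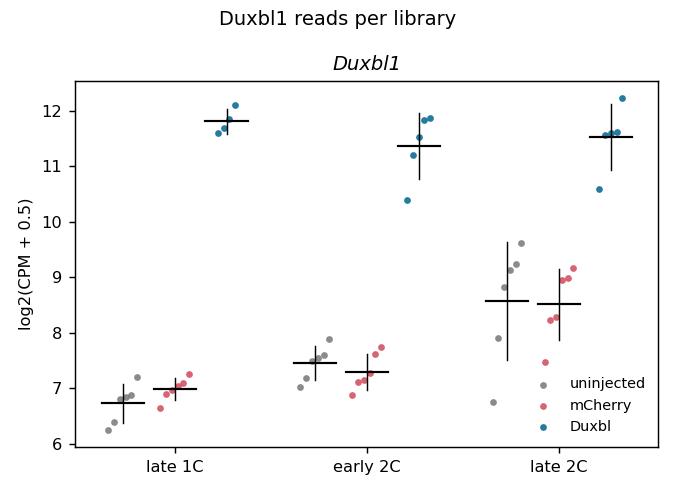
Duxbl1 per library as log2(CPM + 0.5) on the y axis against stage on the x axis. Points are libraries of uninjected (grey), mCherry (red) and Duxbl (blue) embryos, and black lines are the mean and SD of the log2 values; every blue point lies above the red and grey points of its stage.

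The uninjected libraries gave the normal course between stages. From late 1C to early 2C, 871 of 20791 genes passed the test, 367 higher and 504 lower at early 2C (n = 6 per stage). Among higher genes that met the naming rule, Eif1ad8 went from 1.09 ± 0.55 to 63.4 ± 30.6 CPM (log2 5.11, SE 0.44, adjusted p = 2.43e-07) and Zscan4f, a zinc finger protein of the 2-cell stage, from 0.488 ± 0.411 to 28.4 ± 14.8 CPM (log2 4.68, SE 0.45, adjusted p = 1.06e-06). Eif1ad10, Pramel17 and Eif1ad7 followed, with log2 fold changes of 4.62, 4.52 and 4.39. Gnl2, a nucleolar GTPase of ribosome assembly, Frg1, Txnip, Ercc5 and Dnttip2 fell, with log2 fold changes of -2.60, -2.58, -2.53, -2.48 and -2.47.

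From early 2C to late 2C, 15104 of 20791 genes passed, 7166 higher and 7938 lower at late 2C. AA414992 rose from 0.12 ± 0.139 to 286 ± 197 CPM (log2 8.13, SE 0.65, adjusted p = 1.71e-10), and Obox8, an oocyte-specific-type homeobox gene, from 3.73 ± 2.7 to 893 ± 613 CPM (log2 7.54, SE 0.44, adjusted p = 1.09e-12). Exoc3l2 and Ifi35 rose by log2 fold changes of 7.77 and 7.18. Npffr2, Ccdc105, Ccdc3, Ifit1bl2 and the gap junction gene Gja4 fell, with log2 fold changes of -5.82, -5.77, -5.75, -5.71 and -5.60. Duxf3 fell from 4.74 ± 1.48 to 0.332 ± 0.676 CPM (log2 -2.86, SE 0.45, adjusted p = 6.41e-06). The median change over all tested genes was -0.148, and 0.097 with median of ratios scaling. Which direction held more genes depended on scaling, since the share of lower genes among the calls was 52.6% here and 46.8% with median of ratios scaling.

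The mCherry libraries were compared with uninjected ones to show what injection and the reporter alone did. limma called 0 of 19507 genes at late 1C, 0 of 20089 at early 2C and 0 of 23277 at late 2C (n = 6 against 6). At an unadjusted p under 0.05 there were 511, 753 and 425 genes, fewer than the 5 in 100 that chance gives. Duxbl1 stood at 128 ± 17.6 CPM in mCherry and 108 ± 25.6 CPM in uninjected late 1C embryos and at 394 ± 152 and 457 ± 247 CPM at late 2C. limma voom also called 0, 0 and 0. With all 9 groups in 1 fit, 0, 1 and 25 genes were called, 21 of the last 25 higher in mCherry. A count of 0 does not show that injection changed nothing. Stage progress at early 2C was 0.81 ± 0.21 in mCherry and 1 ± 0.26 in uninjected embryos, a difference that was not tested.

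At late 1C, 28 to 30 h after hCG and within hours of injection, 4 of 19507 genes differed between Duxbl and mCherry embryos, 1 higher and 3 lower. The higher gene was Duxbl1. The lower genes, named after their values were seen, were Usp17ld (0.0484 ± 0.0479 against 4.98 ± 1.62 CPM, log2 -3.26, SE 0.39, adjusted p = 0.000539), Usp17lc (1.23 ± 0.676 against 9.93 ± 4.56 CPM, log2 -2.57, SE 0.38, adjusted p = 0.00603) and Gm38271 (0.28 ± 0.432 against 4.37 ± 1.52 CPM, log2 -2.72, SE 0.34, adjusted p = 0.000539), with n = 4 and 6. Both Usp17l genes encode deubiquitinases of a multigene family whose copies can share reads. Of 40 tested genes on the list of 2-cell and DUX-responsive genes, 2 were lower and 38 did not pass, and 12 were lower when adjusted over the list alone. The list's median log2 fold change was -0.55 (camera adjusted p = 2.55e-14, and 0.0302 with an estimated correlation).

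Camera at its preset correlation also called cytosolic ribosomal proteins higher (median log2 0.10), nuclear oxidative phosphorylation genes higher (0.15) and interferon genes lower (-0.16). None of their members passed the gene test, and the adjusted p with an estimated correlation was 0.703, 0.703 and 0.189. Genes that rise from late 1C to early 2C in uninjected embryos had a median log2 fold change of -0.48 (adjusted p = 0.0672 with an estimated correlation), and the 17 tested genes that peak at early 2C had a median of -0.75 (adjusted p = 0.0437 likewise). Replicates 4 and 5 lay apart from replicates 1, 3, 6 and 7 in every treatment, so the count was repeated within each. It came to 1 gene (Duxbl and mCherry n = 2 and 2) and 2 genes (n = 2 and 4), and limma voom and a fit of all 9 groups each called 1 gene. In replicates 1, 3, 6 and 7 the calls were 1 higher and 1 lower gene, and in the other settings Duxbl1 alone.

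At early 2C, 32 h after hCG, 105 of 20089 genes differed between Duxbl (n = 5) and mCherry embryos (n = 6), 6 higher and 99 lower. Usp17la stood at 0.338 ± 0.607 CPM in Duxbl and 15.9 ± 9.44 CPM in mCherry embryos (log2 -4.26, SE 0.55, adjusted p = 0.000145), Pramel41 at 0.371 ± 0.376 and 16.6 ± 9.80 CPM (log2 -4.20, SE 0.43, adjusted p = 8.6e-06) and Eif1ad8 at 1.12 ± 0.633 and 28.3 ± 16 CPM (log2 -4.00, SE 0.50, adjusted p = 0.000128). Pramel16, Eif1ad10, Pramel20, Eif1ad2 and Eif1ad6 fell, with log2 fold changes of -3.99, -3.81, -3.68, -3.65 and -3.46.

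By family, a grouping chosen after these calls were seen and so not tested on them, 10 of 16 tested Eif1ad genes, 4 of 5 Usp17l genes, 5 of 9 Zscan4 genes and 9 of 41 Pramel genes were lower and 0 were higher. In the other families counted, 0 of 4 Tdpoz, 1 of 31 Obox and 2 of 371 Zfp genes were lower. Near-identical copies within families such as Eif1ad, Usp17l, Zscan4 and Pramel can share reads, so values of single members are uncertain. Of 47 tested genes on the fixed 2-cell and DUX-responsive list, 15 were lower, 32 did not pass and 0 were higher, and 28 were lower when adjusted over the list alone (median log2 -1.53, adjusted p = 0.00993 with an estimated correlation). Zscan4d, one of them, stood at 7.56 ± 4.31 CPM in Duxbl and 79.2 ± 47.0 CPM in mCherry embryos. A score of this list per library, the mean log2 CPM of its genes, was lower in Duxbl embryos by 0.76 at late 1C and 1.62 at early 2C, with no overlap between the groups (two-sided exact permutation p = 0.00476 and 0.00216, the smallest possible, and 0.109 and 0.0497 adjusted over 23 lists). Within replicates 4 and 5 these differences were -1.13 and -1.66 and within replicates 1, 3, 6 and 7 they were -0.59 and -1.60, with every Duxbl library below. Paired by replicate number, the score was lower in 4 of 4 pairs at late 1C (mean difference -0.87, exact sign-flip p = 0.125) and 5 of 5 at early 2C (-1.62, p = 0.0625), each the smallest possible p with so few pairs, so pairing leaves both above 0.05. The score and its paired test were chosen after the data were seen.

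**Figure D2:**
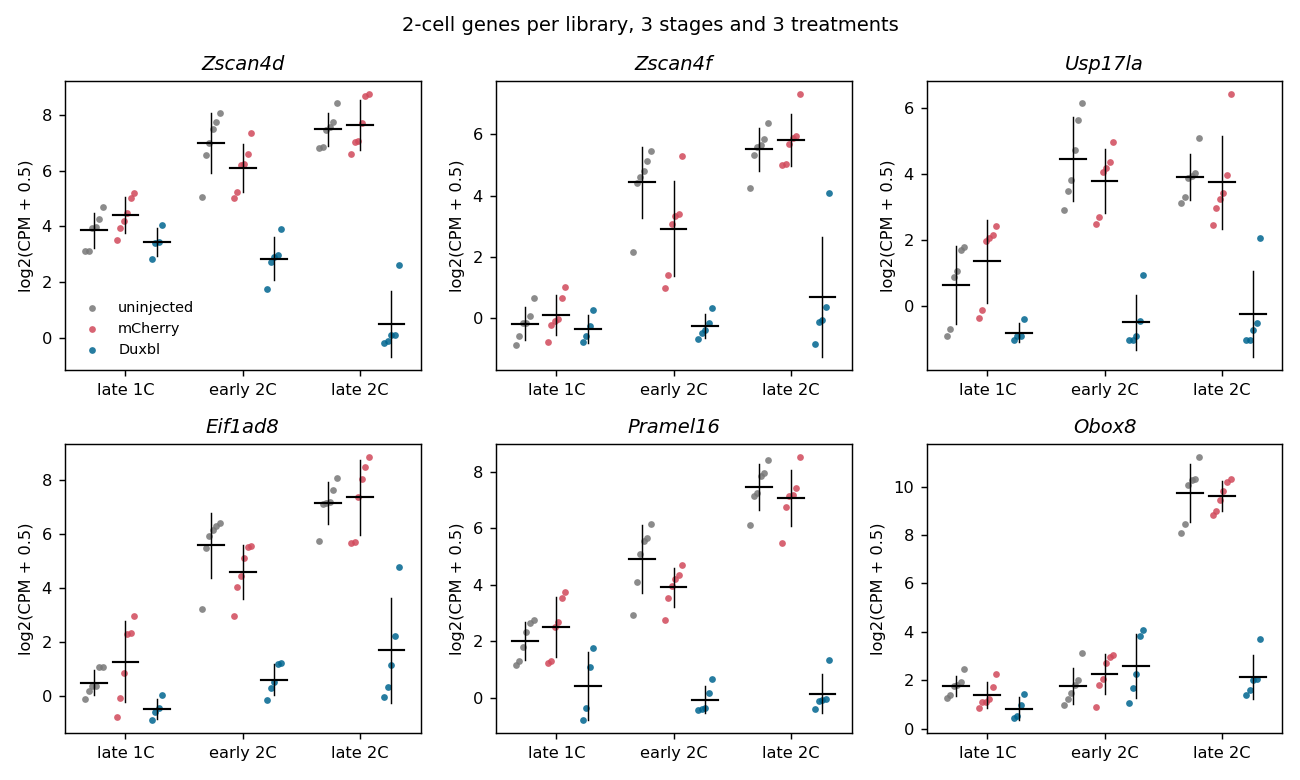
Zscan4d, Zscan4f, Usp17la, Eif1ad8, Pramel16 and Obox8 per library as log2(CPM + 0.5) on the y axis against stage on the x axis. Points are libraries of uninjected (grey), mCherry (red) and Duxbl (blue) embryos, and black lines are the mean and SD of the log2 values; Eif1ad8 averaged 28.3 CPM in mCherry and 1.12 CPM in Duxbl early 2C embryos, and Obox8 averaged 836 and 4.86 CPM at late 2C.

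Of the 6 higher genes at early 2C, 1 was Duxbl1. Gon7, a subunit of a transfer RNA modification complex, stood at 15.0 ± 5.31 against 5.97 ± 1.97 CPM (log2 1.25, SE 0.28, adjusted p = 0.0444). The other 4, named after their values were seen, were low: Wnt5a, a secreted signalling protein (4.98 ± 2.60 against 0.889 ± 0.352 CPM), Hoxd1 (1.23 ± 0.507 against 0.0999 ± 0.109 CPM), Paqr9 and Gm47111, with log2 fold changes of 1.85, 1.48, 1.53 and 2.12. The Gon7 call was lost without any 1 of mCherry replicates 1, 4, 5 and 7 and Duxbl replicates 4, 5, 6 and 7 (adjusted p between 0.0535 and 0.212). The count was 7 genes within replicates 4 and 5 (1 higher, 6 lower), 49 within replicates 1, 3, 6 and 7 (1 higher, 48 lower), 69 without Duxbl replicate 5 and 10 with limma voom (1 higher, 9 lower).

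The lower genes at early 2C were those that normally rise at this point. Of the 99, 88 (88.9%) belonged to the 349 genes that rise from late 1C to early 2C in uninjected embryos, where 1.72 would be shared by independent lists. That set had a median log2 fold change of -1.25 (camera adjusted p = 0.00186 with an estimated correlation), and the set that peaks at early 2C one of -1.73 (adjusted p = 0.000235 likewise). Genes that fall from late 1C to early 2C had a median of -0.12, and 0 of 329 passed (adjusted p = 0.662 likewise). Cytosolic ribosomal proteins (median log2 -0.08) and oocyte and maternal effect genes (-0.10) were called lower by camera at its preset correlation, with 0 members called and an adjusted p of 0.58 and 0.473 with an estimated correlation.

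At late 2C, 48 h after hCG, 12934 of 23277 genes (55.6%) differed between Duxbl (n = 5) and mCherry embryos (n = 6), 5614 higher and 7320 lower. The median change over all tested genes was -0.199, and -0.057 with median of ratios scaling. With all 9 groups in 1 fit 8443 genes were higher and 8401 lower, so which direction held more genes depended on the fit. Obox8 stood at 4.86 ± 4.29 CPM in Duxbl and 836 ± 339 CPM in mCherry embryos (log2 -7.45, SE 0.48, adjusted p = 4.89e-11) and Zscan4a at 0.746 ± 0.542 and 206 ± 66.5 CPM (log2 -7.40, SE 0.38, adjusted p = 2.49e-12). Pramel6, the alkaline phosphatase Alppl2, Trim43a, Zscan4d and Pramel16 fell, with log2 fold changes of -7.33, -7.25, -7.22, -7.13 and -6.94.

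Among higher genes at late 2C that met the naming rule, Nr2f1, a nuclear receptor, stood at 41.8 ± 6.25 CPM in Duxbl and 0.0833 ± 0.0922 CPM in mCherry embryos (log2 6.18, SE 0.40, adjusted p = 4.66e-11). The signalling gene Wnt1 stood at 66.1 ± 49.1 and 0.538 ± 0.951 CPM (log2 6.07, SE 0.60, adjusted p = 2.71e-08) and Hoxb7 at 33.0 ± 11.6 and 0.0697 ± 0.0964 CPM (log2 5.82, SE 0.60, adjusted p = 4.77e-08). Pou3f2, a POU domain factor of neural cells, the formin Inf2, Zic5, Hoxa9 and Npffr1 had log2 fold changes of 5.58, 5.54, 5.14, 5.14 and 4.76. Replicates 1, 3, 6 and 7 alone gave 12763 genes (n = 4 and 4). Replicates 4 and 5 alone gave 5884, 2893 higher and 2991 lower, with 1 Duxbl library that was assumed to vary like the other groups.

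List medians at late 2C are given relative to the median of all tested genes. None of the 23 lists passed camera with an estimated correlation, the lowest adjusted p being 0.0983, so their counts rest on the tests of single genes. The score per library, chosen after seeing the data, differed by -4.35 for the 2-cell list, -2.9 for ribosomal proteins and 1.21 for maternal genes. The groups did not overlap (exact permutation p = 0.00216 each, 0.00276 adjusted over 23 lists). Paired by number, the 2-cell score gave an exact sign-flip p of 0.0625. Scores of trophectoderm, mRNA decay, cumulus and sperm genes overlapped. With 55.6% of genes called, a score cannot show a change beyond that of other genes.

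Of 50 2-cell and DUX-responsive genes, 46 were lower, 3 higher and 1 did not pass (relative median -5.01, adjusted p = 0.173 with an estimated correlation). Examples are Zscan4a and Trim43a, given above, and Trim43b (9.23 ± 7.82 against 744 ± 306 CPM). The higher members included Pramel25, at 687 CPM in mCherry embryos and between 1880 and 3270 CPM in the Duxbl libraries. The 7 Obox genes on the list split, with 3 lower and 4 higher, and before subtraction of the median of all genes their median was 1.41 and their mean -1.97. Obox6 stood at 19.1 ± 12.8 against 1257 ± 452 CPM and Obox3 at 4.54 ± 3.03 against 470 ± 194 CPM, while Obox2 stood at 1192 ± 389 against 343 ± 142 CPM. By family, 17 of 17 Eif1ad, 5 of 5 Usp17l, 9 of 9 Zscan4 and 10 of 10 Tdpoz genes were lower. Of 42 Pramel genes 24 were lower and 12 higher, and of all 24 tested Obox genes 13 were lower and 4 higher. The directions were the same under the other scalings, with the same reservation on near-identical copies.

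Of 74 ribosome biogenesis genes, 67 were lower and 0 higher (relative median -2.39), among them Wdr74 (1.69 ± 1.18 against 237 ± 53.3 CPM), Nob1 (5.59 ± 1.86 against 193 ± 61.1 CPM), Emg1 (23.6 ± 13.2 against 510 ± 130 CPM) and Nhp2 (11.8 ± 6.42 against 430 ± 113 CPM). Of 79 cytosolic ribosomal protein genes, 75 were lower and 0 higher (-2.83), with Rpsa at 8.67 ± 3.26 against 262 ± 64.7 CPM and Rpl19 at 7.61 ± 2.51 against 255 ± 76.6 CPM. Of 41 translation initiation factors, 27 were lower and 1 higher (-1.58), with Eif6 at 30.5 ± 11.2 against 463 ± 158 CPM. Of 53 spliceosome genes, 38 were lower and 4 higher (-1.33), and of 35 proteasome genes, 28 were lower and 1 higher (-1.66). Psmb5, a catalytic proteasome subunit, stood at 2.25 ± 1.58 against 117 ± 51.2 CPM and the spliceosomal protein gene Snrpd2 at 6.83 ± 2.97 against 218 ± 44.8 CPM. The adjusted p with an estimated correlation was 0.173 for each of these 5 lists. Of 75 nuclear oxidative phosphorylation genes, 42 were lower and 6 higher (-0.91, adjusted p = 0.269 likewise), with Ndufs8, of respiratory complex I, at 2.28 ± 1.43 against 221 ± 36.5 CPM.

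Oocyte and maternal effect genes went the other way. Of 51, 38 were higher, 13 did not pass and 0 were lower (relative median 1.67, adjusted p = 0.0983 with an estimated correlation). Wee2, an oocyte kinase that holds meiosis, stood at 2104 ± 364 CPM in Duxbl and 546 ± 165 CPM in mCherry embryos. Btg4, an adaptor that directs maternal mRNA to deadenylation, stood at 4037 ± 1090 and 1076 ± 408 CPM, Nlrp9c at 2134 ± 514 and 563 ± 85.9 CPM, and Omt2a at 5544 ± 734 and 2205 ± 497 CPM. Of 40 genes of mRNA deadenylation and decay, 13 were higher and 16 lower (0.02, adjusted p = 0.998 likewise). The deadenylase gene Cnot7 stood at 1916 ± 248 against 605 ± 132 CPM and Cnot10 at 4.98 ± 3.37 against 82.0 ± 17.4 CPM. That list's median was -0.18 here and 0.01 with median of ratios scaling.

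Cell cycle and stress lists were lower in most called members. Of 46 DNA replication genes, 26 were lower and 3 higher (-1.19, adjusted p = 0.173 with an estimated correlation), and of 32 genes of G2 and mitosis, 20 were lower and 5 higher (-0.93, adjusted p = 0.269 likewise). Incenp, of the chromosomal passenger complex, stood at 11.7 ± 6.23 against 102 ± 17.9 CPM and Cdc45 at 23.1 ± 12.2 against 218 ± 66.6 CPM, while Orc5 stood at 731 ± 214 against 150 ± 47.7 CPM. Of 27 p53 targets, 13 were lower and 4 higher (-0.98, adjusted p = 0.173 likewise), with the cell cycle inhibitor Cdkn1a at 9.71 ± 5.48 against 146 ± 23.4 CPM. Of 29 heat shock genes, 20 were lower and 5 higher (-1.47, adjusted p = 0.173 likewise). Of 23 genes of ER stress and the integrated stress response, 15 were lower and 2 higher (-1.62, adjusted p = 0.0983 likewise), with Trib3 at 1.2 ± 0.685 against 50.7 ± 13.6 CPM. Of 25 interferon and RNA sensing genes, 11 were lower and 3 higher (-0.28, adjusted p = 0.276 likewise), with Irf7 at 0.522 ± 0.879 against 34.5 ± 13.3 CPM.

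Lineage and chromatin lists were mixed. Of 28 pluripotency factors, 14 were lower and 5 higher (-1.17, adjusted p = 0.173 with an estimated correlation). Dppa4 stood at 14.5 ± 6.56 against 480 ± 124 CPM, Dppa2 at 29.0 ± 8.93 against 359 ± 122 CPM and Klf5 at 10.5 ± 6.69 against 108 ± 36.7 CPM. Of 18 trophectoderm genes, 5 were lower and 4 higher (-0.41, adjusted p = 0.894 likewise). Tead4, a driver of that lineage, stood at 0.148 ± 0.0585 against 22.6 ± 13.7 CPM, and Gata3, another, at 102 ± 14.2 against 15.5 ± 10.4 CPM. Of 40 chromatin repressors, 16 were lower and 9 higher (-0.27, adjusted p = 0.748 likewise). Trim28 stood at 12.6 ± 5.88 against 210 ± 54.7 CPM and Max at 327 ± 55.0 against 69.8 ± 24.7 CPM.

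**Figure D3:**
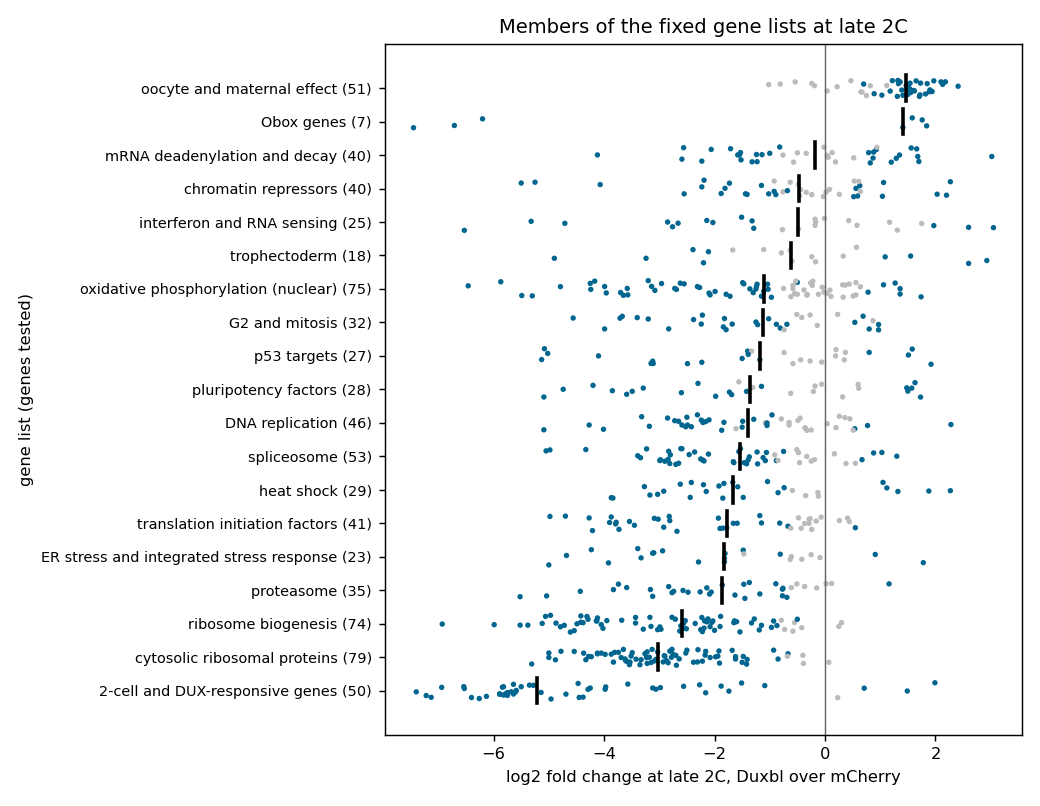
Log2 fold change at late 2C, Duxbl over mCherry, on the x axis for each tested member of 19 fixed gene lists on the y axis. Blue points passed adjusted p under 0.05, grey points did not, and the black bar is the list's median before subtraction of the median of all genes; the 2-cell list lies lowest at -5.21 and oocyte and maternal effect genes highest at 1.47.

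Genes that normally change from early 2C to late 2C changed less in Duxbl embryos. Of 6467 tested genes of the set that rises in uninjected embryos, 6033 rose and 0 fell from early 2C to late 2C in mCherry embryos (median log2 2.34), and 1714 rose and 659 fell in Duxbl embryos (median 0.34). Of 6742 genes of the set that falls, 6063 fell and 1 rose in mCherry embryos (median -1.82), and 2971 fell and 530 rose in Duxbl embryos (median -0.71). Of the 7320 lower genes, 4742 (64.8%) belonged to the 6477 genes that rise over this step in uninjected embryos, where 2040 would be shared by independent lists. Of the 5614 higher genes, 3318 (59.1%) belonged to the genes that fall, where 1470 would be shared. The rising set had a median log2 fold change of -2.24 and the falling set one of 1.32 (camera adjusted p = 9.02e-06 and 0.000594 with an estimated correlation). Of the deposited signal, the genes that rise held 8.55 ± 1.33% in Duxbl and 40.1 ± 2.81% in mCherry late 2C embryos, and the genes that fall held 50.2 ± 2.91% and 22.3 ± 3.01% (SD, n = 5 and 6).

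A stage progress score was set to 0 and 1 at the uninjected means of consecutive stages. At early 2C it was 0.49 ± 0.16 in Duxbl (n = 5) and 0.81 ± 0.21 in mCherry embryos (n = 6), a difference of -0.33 (two-sided exact permutation p = 0.013). The early difference lay in the rising set. From late 1C to early 2C, 136 of its 348 genes rose in mCherry and 12 in Duxbl embryos (median log2 1.43 and 0.67). Of 332 genes of the falling set, 117 and 122 fell (median -0.98 and -1.18). At late 2C the score was 0.27 ± 0.06 and 0.96 ± 0.05, a difference of -0.69 (exact permutation p = 0.00216, the smallest that 462 splits can give), and every Duxbl library lay below every mCherry library. This score covers the stage sets alone, and the whole profile of Duxbl late 2C embryos lay far from each normal stage. Its root mean square log2 distance was 1.69 ± 0.18 from uninjected late 1C, 1.63 ± 0.18 from early 2C and 2.05 ± 0.09 from late 2C embryos (SD, n = 5), against 0.8 ± 0.06 from late 2C for mCherry late 2C embryos (n = 6). Within replicates 1, 3, 6 and 7 the differences were -0.364 and -0.722 (exact permutation p = 0.0286 each), and within replicates 4 and 5 they were -0.295 and -0.609, where no p under 0.333 was possible. With the replicate number as a block (replicate block) they were -0.338 and -0.695 (exact permutation p = 0.0625 each, the smallest possible). Without Duxbl early 2C replicate 6 the early difference was -0.264 (exact permutation p = 0.0524).

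**Figure D4:**
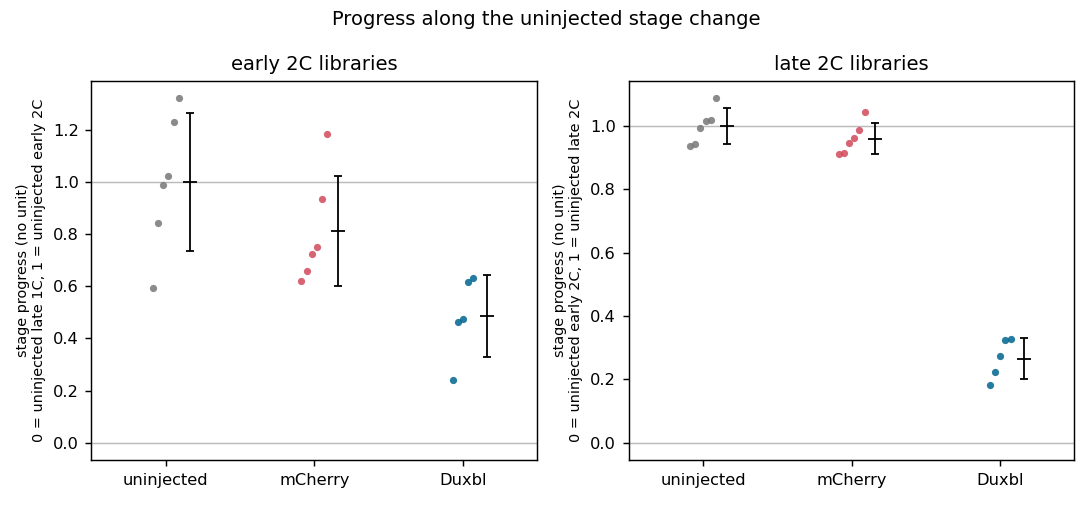
Stage progress (no unit) on the y axis for each library of early 2C (left) and late 2C embryos (right) by treatment on the x axis. Points are libraries and black bars the mean and SD; Duxbl late 2C libraries averaged 0.27 and mCherry libraries 0.96.

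Against uninjected embryos, which share the Duxbl libraries with the comparisons above, Duxbl embryos differed in 3 of 19507 genes at late 1C (1 higher, 2 lower), 176 of 20089 at early 2C (16 higher, 160 lower) and 13237 of 23277 at late 2C (5901 higher, 7336 lower). At early 2C Pramel16 stood at 0.49 ± 0.358 against 37.4 ± 23.4 CPM (log2 -4.99, SE 0.46, adjusted p = 2.03e-06), and Eif1ad8, Usp17la, Eif1ad10 and Zscan4f fell, with log2 fold changes of -4.97, -4.93, -4.74 and -4.71. Uhrf2 and the heterochromatin gene Bahd1 were higher, with log2 fold changes of 1.95 and 1.23. At late 2C, among genes that met the naming rule, Nr2f1, Wnt1, Inf2, Pou3f2 and Sox1ot were higher, with log2 fold changes of 6.24, 6.11, 5.85, 5.54 and 5.07, and Obox8, Pramel6, Alppl2 and Trim43a fell, with log2 fold changes of -7.58, -7.48, -7.42 and -7.39. Within replicates 4 and 5 the counts were 1, 48 and 5568, within replicates 1, 3, 6 and 7 they were 1, 73 and 13527, and limma voom called 1 and 32 at late 1C and early 2C.

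Whether the effect of Duxbl differed between stages was tested as an interaction. From late 1C to early 2C limma called 0 of 26310 genes (472 at an unadjusted p under 0.05, n = 4 to 6 per group), and limma voom called 0. From early 2C to late 2C it called 12364, of which the effect was more positive at late 2C in 5873 and more negative in 6491.

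Transcripts of other cells that a pool could carry were summed per library. At late 1C, blood genes summed to 13.4 ± 22.1 CPM in Duxbl (n = 4) and 1.6 ± 0.987 CPM in mCherry embryos (n = 6), with 46.4 CPM in Duxbl replicate 6 and at most 5.18 CPM in the other late 1C libraries. At late 2C, cumulus and granulosa genes summed to 68.9 CPM in Duxbl and 83.6 CPM in mCherry embryos, sperm genes to 313 and 150 CPM, oviduct epithelium genes to 203 and 775 CPM, and blood genes to 9.91 and 69.1 CPM. Of these lists' 21, 15, 11 and 7 members, 2, 3, 4 and 3 exceeded 10 CPM in uninjected late 2C embryos, so the sums include genes of the embryo. The sperm sum rested on Odf2 (275 ± 47.9 against 92.3 ± 18.6 CPM) and the oviduct sum on the tubulin gene Tubb4b (57.8 ± 23.8 against 615 ± 195 CPM), whereas Ovgp1, the oviduct glycoprotein, stood at 57.3 ± 31.7 against 6.98 ± 3.93 CPM and Amhr2 at 0.72 ± 0.688 against 44.6 ± 9.30 CPM.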

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

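The tests of Duxbl1 levels and of a smaller total of other transcripts were chosen only after the results were seen. The bounds of the tests on Duxbl1 and on control-like embryos were reset more than once after their values were seen.

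The effect of Duxbl against mCherry differed between early 2C and late 2C in 12364 of 26310 genes by a test of the difference itself (interaction, limma). The late 2C effect exceeded the early 2C effect by 5.11 for Wnt1 (SE 0.67, adjusted p = 1.31e-07) and 4.51 for Nr2f1 on the log2 scale, and the difference was -7.62 for Obox8 (SE 0.67, adjusted p = 6.12e-11).

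Single libraries lay far from the rest of their group in 20 of 318 gene and group combinations (6.29%), where chance gives about 5% (15.9). Duxbl late 2C replicate 7 was highest for Asns (1.52 CPM, others 0.0551 to 0.155), Obox8 (12.4 CPM), Pramel16 (2.05 CPM), Pramel6 (2.57 CPM) and Zscan4d (5.67 CPM, others 0.385 to 0.569). Duxbl late 2C replicate 4 was lowest for Nhp2 (1.91 CPM) and highest for Prm1 (0.47 CPM, others 0), and replicate 1 was highest for Nob1 (8.85 CPM). At early 2C, Duxbl replicate 7 was highest for Eif1ad2 (0.831 CPM) and replicate 4 for Usp17la (1.41 CPM). Among mCherry late 2C libraries, replicate 4 was lowest for Dppa2 (159 CPM), replicate 5 lowest for Tssk6 (3.03 CPM), replicate 6 highest for L3mbtl2 (140 CPM) and Wdr74 (340 CPM), and replicate 3 highest for Wnt1 (2.45 CPM). Among uninjected libraries, early 2C replicate 7 was lowest for Eif1ad8 (8.8 CPM) and Zscan4f (3.94 CPM), early 2C replicate 5 lowest for Ccdc3 (39.7 CPM), late 2C replicate 7 highest for Ccdc105 (0.961 CPM) and late 2C replicate 1 highest for Duxf3 (2.07 CPM).

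Duxbl late 2C replicate 1 held more 2-cell transcripts than the other Duxbl late 2C libraries, above all 4 others in 26 of 50 genes of the 2-cell list, where chance gives 20% for a single gene. The list's genes vary together, so this count is no test. The screen for single libraries also covered the list's score and flagged no Duxbl late 2C library for it. Duxbl1 at collection was not lowest in that pool. It stood at 3111 CPM there and at 1547 CPM in replicate 3. The ratio was 0.497, and the gap exceeded the SD of the other 4 libraries (1333 CPM). Replicate 3 was nevertheless lower in 36 of the 50 genes, with a mean log2 CPM of 1.67 against 3.50. This sets 1 library against 1 other, and Duxbl1 includes endogenous transcripts. The amount at injection was not measured, so less Duxbl mRNA in that pool stays open as a cause. Wholly control-like embryos in the pool are argued against. They would bring all genes that mCherry embryos express and Duxbl embryos lack, and 1 of 5 embryos about 20% of each if embryos hold like amounts of RNA. Such genes stood at a median of 2.01% of their mCherry level off the 2-cell list (172 genes, quartiles 0.407% and 7.18%), 12 of them at 20% or more and 139 below 20% of their lowest mCherry library. Off the list the like median in the other Duxbl late 2C libraries was 0.363% to 1.31%, so replicate 1 was somewhat raised there too, the direction such embryos would bring. On the list the median in replicate 1 was 10.5% (10 genes, quartiles 0.281% and 22.3%), with shares from 0.182% to 81.7% where 1 share was to be expected. The ratio of the medians, 0.192, is under the bound first set, before the values were seen, though the quartiles overlap. The share of 20% that decides here was chosen after they were seen. Embryos with a weaker response stay open, and no biological explanation was tested.

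Genes that fall from early 2C to late 2C in uninjected embryos stood higher in Duxbl than in mCherry late 2C embryos, and shares of a total rise when other transcripts are fewer. A smaller total of other transcripts would raise stable genes alike, but only if the amounts of the stable genes themselves were unchanged. As shares of the deposited total, the falling genes had a median log2 change of 1.11 and the stable genes one of -0.29, a gap of 1.39. The stable genes spread widely (quartiles -1.26 and 0.61), so they are no fixed reference and the gap cannot decide. Amounts per embryo were not measured, so slower loss, fewer other transcripts or both stay open.

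For Duxbl against mCherry, chance was excluded for the counts of genes at late 1C (1 of 100 splits as large, real 4, highest other 1), early 2C (1 of 100, real 105, highest other 26) and late 2C (1 of 100, real 12934, highest other 9213). Each of these counts includes Duxbl1, which was injected. At late 1C the 3 lower genes were lost with limma voom or all 9 groups in the fit. For these genes the splits therefore speak of the main fit alone. Of 8 splits that part as many replicate pairs at late 1C the highest gave 0 genes, and of 6 at early 2C the highest gave 26. For Duxbl against uninjected, chance was excluded at early 2C (2 of 100, real 176, highest other 221) and late 2C (1 of 100, real 13237, highest other 9464). At late 1C 3 of 100 splits gave a count as large (real 3, highest other 570). That count of 1 higher and 2 lower genes includes Duxbl1, and it fell to 1 gene with limma voom or all 9 groups in the fit. The splits therefore do not exclude chance for the 2 lower genes. Splits that part as many pairs gave at most 0 at the first 2 stages. The splits with 570 and 221 genes point to a structure of the samples. A split of late 1C mCherry and Duxbl libraries by replicates 4 and 5 called 1541 genes, against 4 for the real split, and the report gives values within these replicates. Chance was excluded for the uninjected stages (1 of 100 each, real 871 and 15104, highest other 144 and 9923) and for the interaction from early 2C to late 2C (1 of 100, highest other 8749). A count of 0 is matched by any split, 100 of 100, so the splits say nothing of chance for mCherry against uninjected (highest other 1, 157 and 488) or the interaction from late 1C to early 2C (highest other 1).

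For lists at the preset correlation, chance was not excluded at late 1C (19 of 100 splits, real 4, highest other 7) or early 2C (47 of 100, real 3, highest other 10). At late 2C it was excluded by the count alone (4 of 100, real 15, highest other 15), but the median of the other splits was already 9 lists. With an estimated correlation 0 lists were called there, so this exclusion is weak. With 5 stage sets the count is too coarse to decide, since the median of the other splits was 2, 3 and 4 at the 3 stages, and the splits say nothing of chance for it (28 of 100 as large at late 1C, real 3, 55 of 100 at early 2C, real 3, and 78 of 100 at late 2C, real 4, highest other 5 each).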

How the results depend on the processing

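The settings with pseudocounts of 0.1 and 1, the deposited scale, a batch term and replicates taken apart were chosen only after the results were seen, and the cause of the changes given here was not tested unless fewer libraries or groups are named. Median of ratios scaling, the deposited scale, a pseudocount of 0.1, a set threshold of 2 and the replicate block moved no count of genes, lists or sets by over 1.5 times. The share of lower genes among late 2C calls, Duxbl against mCherry, went from 56.6% to 52.2% with median of ratios scaling and 49.9% with all 9 groups in the fit, where the higher genes went from 5614 to 8443. The Wald test of DESeq2 was not run, since the values are not counts.

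With no filter, Duxbl against uninjected at late 1C called 1 gene. A pseudocount of 1 gave 1 there and 1 in the interaction from late 1C to early 2C. A batch term for replicates 4 and 5 called 5 lists at early 2C. limma voom called 1 and 10 genes in Duxbl against mCherry at late 1C and early 2C, 1 and 32 in Duxbl against uninjected, and 1760 between uninjected late 1C and early 2C. All 9 groups in the fit gave 1 gene at late 1C in Duxbl against mCherry and 1 against uninjected, 1 and 25 in mCherry against uninjected at early 2C and late 2C, and 2 in the interaction from late 1C to early 2C. Only the 2 groups compared gave 1 in Duxbl against uninjected at late 1C. With an estimated correlation, Duxbl against mCherry called 1, 1 and 0 lists at the 3 stages and 1 stage set at late 1C.

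Replicates 4 and 5 alone, with fewer libraries, gave 1, 7 and 5884 genes in Duxbl against mCherry and 1, 48 and 5568 against uninjected. Of 138 named genes 105 kept direction and threshold, the late 2C progress difference was -0.609, and Tnfaip6 turned to 0.02. Replicates 1, 3, 6 and 7 alone gave 2 and 49 genes at late 1C and early 2C against mCherry, and 1 and 73 against uninjected.

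Leaving out single libraries gave 69 to 121 genes at early 2C in Duxbl against mCherry (69 without Duxbl replicate 5), 1 to 5 in Duxbl against uninjected at late 1C, and 0 to 2 in the interaction from late 1C to early 2C. Lists ranged from 2 to 6 at late 1C and 2 to 5 at early 2C, and early progress from -0.368 to -0.25.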

Other observations

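The groups of developmental genes, the tests on RNA of cumulus, sperm, oviduct and blood cells, the set of genes above the control stages and the test on its rise at early 2C were chosen only after the results were seen.

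Hox genes pattern the body axis later in development. At late 2C, 21 of 30 tested were higher and 1 lower in Duxbl (n = 5) than in mCherry embryos (n = 6), with the same counts under the other scalings. The families were chosen because members led the higher genes, so the counts are not a test of enrichment. Hoxa7 stood at 271 ± 36.5 against 83.6 ± 22.6 CPM, Hoxa9 at 72.2 ± 34.6 against 4.39 ± 7.71 CPM and Hoxd13 at 58.3 ± 32.6 against 5.43 ± 5.08 CPM. Of 14 POU genes, 9 were higher and 4 lower, with Pou4f1 at 278 ± 39.2 against 69.5 ± 15.4 CPM. Of 37 Fox genes, 16 were higher and 3 lower, and of 23 nuclear receptor genes, 11 were higher and 6 lower. Nr2e1 stood at 228 ± 22.1 against 26.9 ± 21.8 CPM. Of 16 Klf genes, 3 were higher and 7 lower. Of the other 8 families counted, Lhx had 5 higher and 0 lower of 8, Zic 3 and 1 of 4, Pax 3 and 1 of 6, Sox 6 and 2 of 18, Tbx 5 and 2 of 15, Wnt 4 and 2 of 17, Nkx 3 and 2 of 11 and Gata 2 and 2 of 5. The share of higher genes among all tested would give 4.1 for Wnt, 2.65 for Nkx, 4.34 for Sox, 3.62 for Tbx, 1.21 for Gata and 3.86 for Klf, so these families lay near it, against 1.93 for Lhx, 0.965 for Zic, 1.45 for Pax, 7.24 for Hox, 3.38 for POU, 8.92 for Fox and 5.55 for nuclear receptors. Under the other scalings counts of higher or lower genes moved by at most 2 in the Fox, POU, Wnt and Klf families and stayed in the rest.

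For the Hox rise, 11 fibroblast genes changed by -41.5 CPM in sum (101 ± 38.1 against 143 ± 49.2 CPM, two-sided exact permutation p = 0.177) while 39 Hox genes gained 506 CPM. The listed genes already had signal in mCherry embryos, so a fall of embryo transcripts could hide a gain. Even the whole sum, at most 156 CPM in a Duxbl library, lay below the lowest Hox gain of 441 CPM. RNA of fibroblasts is argued against on that ground. The explanation was first set as RNA of any other cell and was narrowed to fibroblasts after the value was seen. RNA of the cells on the other 4 lists is argued against as well. Even if their whole sums came from such cells, these stayed below the Hox gain in each Duxbl library, at most 0.16 of it for cumulus and granulosa, 0.852 for sperm, 0.5 for oviduct epithelium and 0.0331 for blood cells. The sums were 68.9, 313, 203 and 9.91 CPM in Duxbl and 83.6, 150, 775 and 69.1 CPM in mCherry embryos, so the sperm sum alone rose, through Odf2 (275 ± 47.9 against 92.3 ± 18.6 CPM). Of 7 tested oviduct genes 1 was higher (Ovgp1) and 3 lower. These arguments, that on fibroblasts included, hold only if such cells carry more of their listed transcripts than of Hox transcripts, which was not measured. Cell types without a list stay open. Background reads over silent genes stay open. Summed olfactory and vomeronasal receptor genes, silent in most tissues, stood at 1180 ± 76.5 against 514 ± 89.1 CPM (log2 1.21, 627 genes), which is 0.531 of the Hox log2 fold of 2.29 and just past the bound of 0.5 set beforehand (exact permutation p = 0.00216 for the receptor sum, the smallest possible). By that bound, background of this kind could account for part of the Hox rise. The receptor genes gained 666 CPM over 627 genes, though, and the Hox genes 506 CPM over 39 genes, far more per gene. This comparison was not set beforehand. It took no account of gene length or of starting levels, which were 137 CPM for Hox and 514 CPM for receptor genes in mCherry embryos. It therefore does not decide whether background could be the whole cause. A response of the embryo to Duxbl stays open as well.

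A set of 319 genes was taken from those higher at late 2C that had a mean of at least 10 CPM in Duxbl embryos. They stood there at 4 or more times their level in every uninjected stage and in mCherry late 2C embryos. Among them were 188 protein coding genes and 84 lncRNA genes. The set also holds receptor genes, such as Olfr310 (28.2 CPM in Duxbl and 2.91 CPM in mCherry late 2C embryos) and Vmn2r63 (14.5 and 1.21 CPM). Background reads over silent genes were not tested for this set and stay open for it. A hypothesis is that the rise begins at early 2C. There 198 of 230 tested genes (86.1%) had higher values in Duxbl than in mCherry embryos, with a median log2 fold change of 0.36, against 51.1% of other genes at the same mean levels. Of the set 2 passed on their own. The set's camera p with an estimated correlation was 0.0486, close to the threshold, and a score of the set per library differed by 0.41 (exact permutation p = 0.0952). At late 1C the camera p was 0.174. An earlier start may thus hold, but it rests on 1 of the 2 tests, and neither test used the replicate numbers.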
